A study of Bacillus subtilis subsp. subtilis str. 168 with 7 samples.

How the data were processed

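Total RNA of Bacillus subtilis 168 was hybridised to Affymetrix arrays at 7 time points of growth after a 100-fold dilution of an overnight culture, with biotin-labelled cRNA made from 6 µg of RNA, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale. The intensities were made with MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited values had a mean near 500 on each array after trimming 2% at each end, as computed here from the table, which is the form that global scaling gives. Every column of the table belonged to 1 of the 7 samples, and 0 columns were left without a sample.

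The table has 5033 probe sets, of which 33 are Affymetrix controls, 4381 are for genes, 606 are for intergenic stretches and 13 are other controls. Names of 2978 gene probe sets came from the platform annotation, which can be old, and 1403 were taken from the probe set's own ID. Where both gave a name, 2938 of 2942 were identical. The 4381 gene probe sets stand for 4130 names, and 2798 of these equal a current symbol in the RefSeq gene table of assembly ASM904v1, which was used for names alone. A gene with several probe sets (85 genes) was represented by the one with the highest mean over the 7 arrays. In 75 of these genes all probe sets had the same sign between stationary and exponential phase. Of 757 genes in 35 lists, 629 were found under the same name, 120 under an older name, and 8 were not matched. The older names rest on general knowledge of the nomenclature and were written down after the probe set names were seen and before any comparison was computed. The build of the coordinates in the intergenic IDs is not given in the sources used here, and they were used only to order probe sets along the chromosome, with the origin at 0 and the largest coordinate as its length.

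Values were taken as deposited, 16 was added, and log2 was taken. Fold changes are on this scale and understate changes of dim genes. The 5000 probe sets other than Affymetrix controls were tested without a filter in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend in the prior spread, two-sided, with Benjamini-Hochberg adjustment over the 5000 probe sets and a threshold of 0.05. Growth phase as a factor was fitted to all 7 arrays for the 3 comparisons between phases, with 4 residual degrees of freedom. For change within a phase, a slope on time within the exponential phase (per 20 min) and within the stationary phase (per 60 min) was added, which left 2 residual degrees of freedom. In that fit the estimated prior degrees of freedom were infinite, so that all genes were taken to share the spread given by the trend. Counts of genes use 1 probe set per gene.

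Gene lists of 3 or more measured members were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry. Benjamini-Hochberg adjustment was over the 35 lists. With an estimated correlation, camera also takes its degrees of freedom from the fit (4 between phases, 2 for slopes). Few lists could then pass between phases and hardly any for slopes, whatever the correlation of their genes. Fry called 2 lists between stationary and exponential phase, purine biosynthesis (fry adjusted p = 0.0271) and motility and chemotaxis (0.000911). It called 1 between transition and exponential, 0 between stationary and transition, 2 within the exponential and 0 within the stationary phase. The lists covered translation, nucleotide and energy metabolism, sugar and amino acid use, fatty acids, transport, proteases, competence, motility, sporulation stages, stress regulons, toxins, biofilm, secondary metabolites, nutrient limitation, cell division, a prophage and Rap and Phr genes. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined.

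The rule for stationary against exponential phase named the 8 largest rises and 8 largest falls past the threshold with no overlap between the phases, up to 2 members per list, and 20 regulators and markers. For the other comparisons it named the 5 largest rises and falls past the threshold. Where no gene passed, between the transition array and the other phases, the 5 largest each way by moderated statistic were given, a choice made after the values were seen. Other genes named were chosen after their values were seen, unless they belong to a list whose result is described.

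The procedure was tested on simulated data drawn from the levels and spread of the 5000 probe sets, in 5 runs with 200 changed probe sets each. The noise was drawn independently for each probe set and array around a constant level. In the data, change with time within a phase is part of the spread and can be shared by many genes. The shares below therefore do not measure false calls in the data. For stationary against exponential phase the procedure recovered 14.8% of 2-fold and 88.2% of 4-fold changes, with 5.50% of simulated calls false. For transition against exponential phase it recovered 2.2% and 37.2%, and for stationary against transition 1.6% and 38.8%. For the slopes the same changes were per time step, and so larger across a phase. Of these it recovered 83.4% and 100% within exponential phase and 85.2% and 100% within stationary phase. The simulated noise had the shared spread that the slope fit assumes, so these shares rest on that assumption and are not comparable with the others. In 20 runs camera at the preset correlation found the shifted list of 20 genes each time and called 1 of the unchanged lists. The genes of these simulated lists were drawn independently. The runs therefore do not measure false calls among lists of correlated genes, such as ATP synthase (estimated correlation 0.98).

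Alternatives were a pseudocount of 1 or 64, quantile normalization, equal array medians, a filter at the 25th percentile of mean level, eBayes without a trend, and leaving out each array. For stationary against exponential phase they also included the 6 arrays of these phases alone, the fit with slopes, and a linear trend in time or in optical density. Subtraction of each array's median intergenic intensity, with a floor at 0 and rescaling, was added after the data were seen.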

Results

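Transcript levels were measured with Affymetrix arrays in Bacillus subtilis 168, a laboratory strain of a Gram-positive, spore-forming soil bacterium, sampled 7 times along growth in a rich broth with 0.2% glucose at 37 °C. Each time point was 1 array. The exponential phase was represented by 3 arrays, taken at 200, 220 and 240 min (optical density at 600 nm of 0.55, 1.05 and 1.36). The transition phase had 1 array at 260 min (2.12), and the stationary phase had 3 arrays at 300, 360 and 420 min (2.30, 2.35 and 2.62). The arrays of a phase served as its replicates, so that the spread within a phase held both noise and change with time. The labels do not say whether the arrays came from separate cultures. The p values of comparisons between phases therefore measure only the spread between these arrays, which may be technical. Those of slopes within a phase rest on departure from a straight line, with a spread shared by genes of similar level. The number of arrays limits the precision of every value below.

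The 240 and 260 min arrays correlated at r = 0.938 across 5000 probe sets and the 260 and 300 min arrays at 0.941 (genes are not independent replicates). The 200 min array correlated at 0.912 with 220 min, 0.777 with 240 min, 0.743 with 260 min, 0.787 with 300 min, 0.779 with 360 min and 0.702 with 420 min, which is not in the order of sampling. The 200 min array stood apart in its dim probe sets. Its intergenic probe sets had a median intensity of 84.1, against 194 to 280.0 on the other 6 arrays, and its gene probe sets had a median of 252 against 350.3 to 436. The median of the Bio and Cre control probe sets, which target sequences of other organisms, lay between 1.82 and 2.38 on 6 arrays and at 12.8 at 360 min. Values of dim genes at 200 min are given with this difference in mind wherever a dim group is described.

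**Figure D1:**
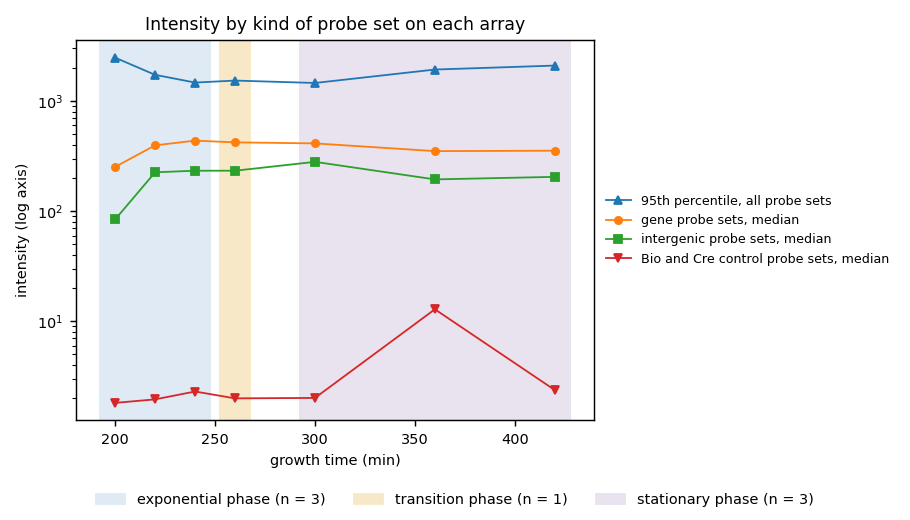
Median intensity of gene, intergenic and Bio and Cre control probe sets and the 95th percentile of all probe sets (log axis) against growth time in minutes, 1 point per array, with shading for the 3 phases. The intergenic median is 84.1 at 200 min and lies between 194 and 280.0 on the other arrays.

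The comparison of stationary with exponential phase asked which genes differ between these phases. Genes of purine nucleotide synthesis showed the largest falls. The intensity of purA, which encodes adenylosuccinate synthetase, averaged 3254 ± 1376 in exponential phase (SD, n = 3) and 239 ± 62.8 in stationary phase (SD, n = 3), a log2 change of -3.60 ± 0.37 (SE). The largest rises were those of the pst operon, which encodes a high-affinity phosphate transporter. Its binding protein gene yqgG (now pstS) went from 278 ± 257 to 2983 ± 1638 (SD, n = 3 each), a log2 change of 3.61 ± 0.61 (SE). In all, 25 of 4130 genes rose and 55 fell (limma, Benjamini-Hochberg threshold of 0.05), and each changed by at least 2-fold.

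Of the 15 purine genes measured, 13 fell and 0 rose, and 15 fell when adjusted over the list alone. Beside purA, the falls of purH (-3.27 ± 0.33 on the log2 scale), purF (-3.27 ± 0.32), purM (-3.25 ± 0.34), purQ (-3.15 ± 0.36) and purN (-3.13 ± 0.32) were the largest, with limma adjusted p values (Benjamini-Hochberg) of 0.000419, 0.000419, 0.000419, 0.000843 and 0.000419. These genes encode enzymes of the pathway from phosphoribosyl pyrophosphate to IMP. All 3 exponential intensities of each lay above all 3 stationary ones, which the rule that named them required. The remaining pair of the 8 largest falls were ysbA (-3.06 ± 0.35), a membrane protein gene, and oppA (-3.06 ± 0.29), the binding protein of the oligopeptide permease, with limma adjusted p = 0.000843 and 0.000419 (Benjamini-Hochberg). In the list of peptide and amino acid transport genes repressed by CodY, 4 of 15 fell and 0 rose (5 fell when adjusted over the list alone). All were opp genes, such as oppF (-1.88 ± 0.26, limma Benjamini-Hochberg adjusted p = 0.00409). The list's median was 0.54, opposite in sign to its mean of -0.23, and its camera test was not passed (adjusted p = 0.0729).

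Of 10 genes of branched-chain amino acid synthesis, 3 fell and 0 rose (6 fell when adjusted over the list alone). Among them, ilvC, which encodes ketol-acid reductoisomerase, changed by -1.98 ± 0.29 and ilvN (now ilvH), an acetolactate synthase subunit, by -1.92 ± 0.34 (limma, Benjamini-Hochberg adjusted p = 0.00677 and 0.0198). In the amino acid catabolism list, 1 of 29 genes fell, the alanine dehydrogenase gene ald (-1.88 ± 0.30, limma Benjamini-Hochberg adjusted p = 0.0106). The count was the same adjusted over the list alone, and the list did not pass the camera test (adjusted p = 0.782, median 0.11). In the motility and chemotaxis list, 8 of 45 genes fell and 0 rose, or 16 adjusted over the list alone. They included the flagellar chaperone gene fliS (-1.90 ± 0.34) and the filament cap gene fliD (-1.83 ± 0.30), with limma adjusted p values of 0.0209 and 0.0128 (Benjamini-Hochberg). The flagellin gene hag stayed bright on all 7 arrays, with a log2 difference of -0.21 ± 0.64 (limma, Benjamini-Hochberg adjusted p = 0.909).

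In the phosphate starvation list, 5 of 19 genes rose and 0 fell, also when adjusted over the list alone. All 5 belong to the pst operon. The changes of yqgJ (pstBA, 3.68 ± 0.67), yqgK (pstBB, 3.35 ± 0.62) and yqgH (pstC, 2.94 ± 0.60) had limma adjusted p values of 0.0217, 0.0229 and 0.0337 (Benjamini-Hochberg). The alkaline phosphatase gene phoA (0.19 ± 0.46) and the regulator gene phoP (0.015 ± 0.28) were among the 14 genes that did not pass. The list's median relative to all genes was -0.010, although its camera test pointed up (adjusted p = 0.0190, and adjusted p = 0.975 with an estimated correlation). The other 3 of the 8 largest rises were the fructose operon genes fruA (2.18 ± 0.49), fruB (2.05 ± 0.45) and fruR (2.05 ± 0.46), with limma adjusted p = 0.0492, 0.0453 and 0.0466 (Benjamini-Hochberg). With 1 array left out their lowest changes were 1.56, 1.498 and 1.52, and the lowest of a pst gene was 2.23 (yqgH).

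**Figure D2:**
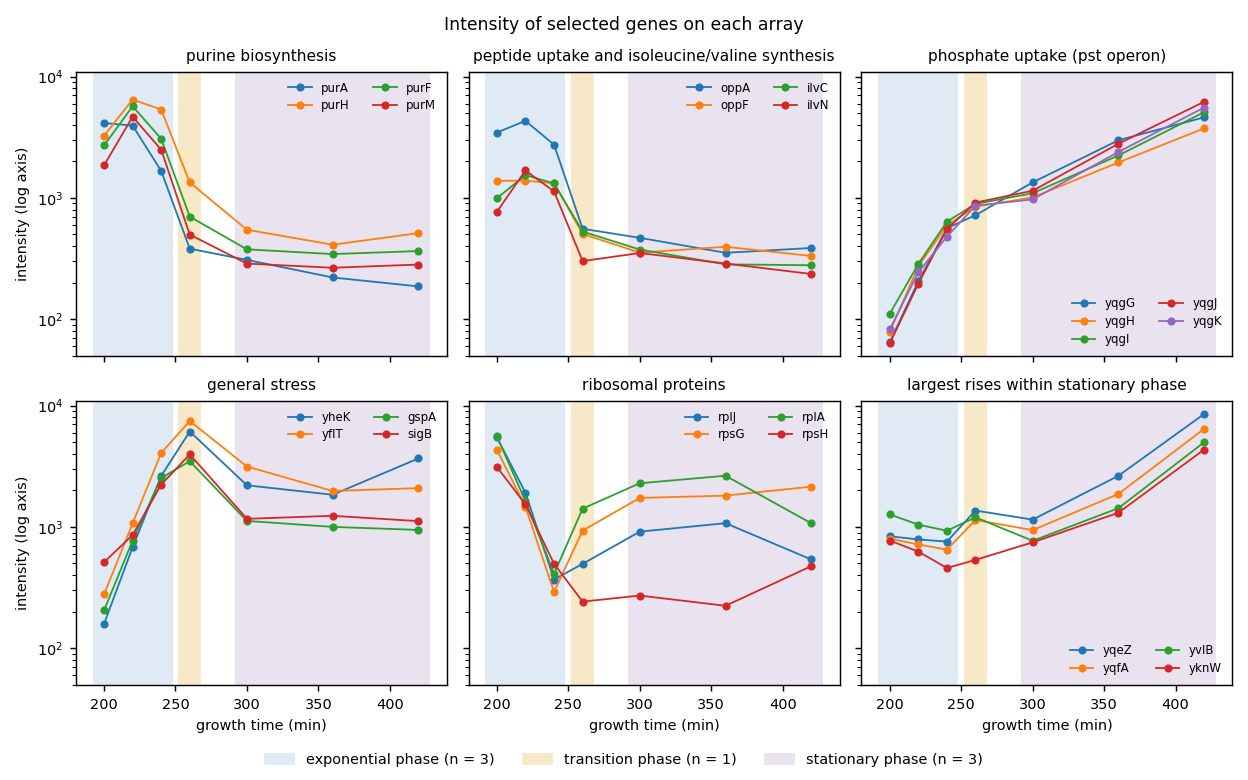
Intensity (log axis) of selected genes against growth time in minutes, 1 point per array and 1 line per gene, with shading for the 3 phases. The purine gene purA goes from 4148 at 200 min to 186 at 420 min, yqgJ of the pst operon from 63.2 to 6201, and the general stress gene yheK peaks at 6119.8 at 260 min.

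Among the 35 gene lists fixed before the data were examined, 4 lay higher and 12 lower than other genes in camera with a preset correlation of 0.01. With an estimated correlation, the motility and chemotaxis list alone remained (adjusted p = 0.0148, against 6.54e-18 with the preset value). The estimated correlation of that list was -0.0062, below the preset value. Its weaker result therefore came from the 4 residual degrees of freedom that this form of camera uses, not from correlation between its genes. Without the 200 min array the calls of the purine, branched-chain amino acid, aminoacyl-tRNA synthetase, ATP synthase, motility and oxygen limitation lists stayed and those of the rest ended. With the intergenic median subtracted, those of the purine, branched-chain amino acid, aminoacyl-tRNA synthetase, ATP synthase, motility, competence, SigK-dependent sporulation and iron acquisition lists stayed. The median of all genes moved by 0.17 between the phases. List medians of the comparisons between phases below are relative to the median of all genes in the same comparison. Median slopes within a phase are given as fitted, unless called relative. Purine genes had a median of -3.18 (camera adjusted p = 6.03e-28, adjusted p = 0.204 with an estimated correlation) and branched-chain amino acid genes -1.05 (5.20e-07, adjusted p = 0.605 with an estimated correlation). Fry called the purine list (fry adjusted p = 0.0271) and not the branched-chain list (0.0981). Of 21 aminoacyl-tRNA synthetase genes, 1 fell, ileS (-1.42 ± 0.32, limma Benjamini-Hochberg adjusted p = 0.0496), and 14 fell when adjusted over the list alone (median -1.17, camera adjusted p = 4.74e-12, adjusted p = 0.605 with an estimated correlation).

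No gene passed in the ribosomal protein list of 52 genes, and 11 fell when adjusted over the list alone (median -0.67, camera adjusted p = 6.47e-05, adjusted p = 0.975 with an estimated correlation). Without the 200 min array the ribosomal protein median was 0.24 and the camera test was not passed (adjusted p = 0.821). The largest differences were those of rpsH (-2.07 ± 0.54) and rplF (-2.06 ± 0.55). Pyrimidine synthesis genes had a median of -1.54 with 0 of 10 past the threshold and 5 lower when adjusted over the list alone (camera adjusted p = 0.000400, adjusted p = 0.952 with an estimated correlation), as in pyrE (-1.98 ± 0.57) and pyrF (-1.73 ± 0.54). The 9 ATP synthase genes had a median of -1.32 with 0 past the threshold (3.09e-05, adjusted p = 0.916 with an estimated correlation). In the oxygen limitation list, 1 of 24 genes fell, the regulator gene fnr (-1.42 ± 0.29, limma Benjamini-Hochberg adjusted p = 0.0337), 2 fell when adjusted over the list alone, and the median was -0.87 (camera adjusted p = 0.00220, adjusted p = 0.373 with an estimated correlation).

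The other lists that lay lower in camera held 0 genes past the threshold. They were fatty acid biosynthesis (median -0.38, adjusted p = 0.00408, adjusted p = 0.952 with an estimated correlation), iron acquisition (-0.51, 0.00408, adjusted p = 0.952 with an estimated correlation), cell division and wall synthesis (-0.63, 0.00466, adjusted p = 0.975 with an estimated correlation) and heat shock (-0.65, 0.0125, adjusted p = 0.605 with an estimated correlation). Examples were accC (-1.38 ± 0.39), feuA (-1.34 ± 0.50), mreC (-0.95 ± 0.44) and groEL (-1.57 ± 0.43).

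None of the members of the other lists that lay higher passed over all genes. They were competence (median 0.47, camera adjusted p = 0.0274, adjusted p = 0.975 with an estimated correlation), SigE-dependent sporulation (0.43, 0.0117, adjusted p = 0.975 with an estimated correlation) and late SigK-dependent sporulation (0.37, 0.0282, adjusted p = 0.975 with an estimated correlation). The values of cgeA (68.3 at 200 min and 222 at 220 min) and spoIIIAG (70.3 and 208) moved as the intergenic median did (84.1 and 225). In the competence list, recA (1.23 ± 0.31) and addA (1.16 ± 0.37), which encode DNA repair and recombination proteins, had the largest differences, and 1 gene rose when adjusted over the list alone.

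The remaining 17 lists beside CodY-repressed transport and amino acid catabolism did not pass. Among them, SigB-dependent general stress genes had a median of -0.014 (camera adjusted p = 0.673), early sporulation 0.20 (0.242), forespore sporulation 0.41 (0.119), biofilm matrix -0.20 (0.673), cannibalism toxins -1.20e-05 (0.782), secondary metabolites -0.028 (0.782) and extracellular proteases -0.075 (0.673). For central metabolism the medians were -0.053 for glycolysis (0.190), 0.072 for the TCA cycle (0.793), 0.10 for acetate and acetoin (0.259), -0.046 for CcpA-repressed sugar use (0.907) and 0.22 for fatty acid degradation (0.101). The last were -0.31 for translation factors (0.410), -0.18 for RNA polymerase and replication (0.673), -0.24 for nitrogen limitation (0.470), -0.013 for the PBSX prophage (0.884) and -0.012 for Rap and Phr genes (0.905). The general stress list passed in camera without the 240 min array (median 0.37, adjusted p = 0.000469, and adjusted p = 0.814 with an estimated correlation). No member of these lists passed over all genes, and adjusted over the list alone 1 biofilm gene and 3 Rap and Phr genes rose and 1 acetate gene and 1 Rap or Phr gene fell. The test pointed up against a relative median below 0 for general stress, cannibalism, secondary metabolites, CcpA-repressed sugar use, PBSX and Rap and Phr genes, and down against a median above 0 for acetate and acetoin.

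Of the 20 regulators and markers named in advance, none passed. The nearest was sinR, the repressor of biofilm genes (1.16 ± 0.29, limma Benjamini-Hochberg adjusted p = 0.0694), followed by citB, which encodes aconitase (0.83 ± 0.27, 0.163). The sporulation regulator gene spo0A had a difference of 0.88 ± 0.32 and its phosphorelay partner spo0F of -0.73 ± 0.26, with limma adjusted p = 0.223 and 0.214 (Benjamini-Hochberg). The surfactin synthetase gene srfAA read 1543 at 200 min, 1559 at 300 min and 6274 at 420 min (1.15 ± 0.46, 0.270). Differences were -0.65 ± 0.29 for sigD, -0.78 ± 0.36 for cotN (now tasA), -0.48 ± 0.29 for sigH, -0.36 ± 0.32 for abrB, -0.29 ± 0.30 for codY, -0.28 ± 0.29 for ccpA, -0.23 ± 0.36 for ftsZ, 0.13 ± 0.29 for degU and 0.14 ± 0.45 for acsA. They were 0.23 ± 0.44 for sigB, 0.41 ± 0.43 for comK, 0.41 ± 0.40 for aprE, 0.63 ± 0.45 for sigF and 0.66 ± 0.50 for sigE.

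An unadjusted p under 0.05 was found for 619 genes, and 1006 of 4130 genes (24.4%) had no overlap between the 3 arrays of each phase. The share would be 10% if the arrays were interchangeable. They are ordered in time, so steady drift also separates the phases, and the excess cannot tell drift from a difference of phase. The counts changed when single arrays were left out: 131 rose and 167 fell without the 200 min array, 3 and 15 without 220 min, 215 and 301 without 240 min, 38 and 32 without 300 min, 0 and 11 without 360 min, and 0 and 13 without 420 min. Under quantile normalization 107 rose and 120 fell, and with equal array medians 0 and 12. With each array's intergenic median subtracted, chosen after the data were seen, 22 rose and 53 fell, and 30 of the 80 genes were among them. Of the 80 genes, 11 passed without each of the 7 arrays in turn: purA, purH, purF, purM, purQ, purN, purD, oppA, oppF, ysbA and ysbB.

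The transition array at 260 min was compared with the exponential phase to see which changes were already present. No gene passed (limma, Benjamini-Hochberg, smallest adjusted p = 0.165), and 205 genes had an unadjusted p under 0.05. General stress genes stood highest. Their list had a median of 1.18 relative to all genes, with 39 of 40 members above 0 (camera adjusted p = 5.62e-17, adjusted p = 0.689 with an estimated correlation). The highest by moderated statistic, taken after the values were seen because none passed, were ydbD (2.44 ± 0.63), rsbX (2.12 ± 0.58), a phosphatase of the SigB pathway, ctc (1.83 ± 0.53), yxiS (1.30 ± 0.41) and dhaS (1.33 ± 0.42). The sigB gene itself read 2237 at 240 min, 3959 at 260 min and 1167 at 300 min.

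Purine genes stood lowest at 260 min, with a list median of -2.73 (camera adjusted p = 2.83e-30, adjusted p = 0.177 with an estimated correlation) and 14 of 15 genes lower when adjusted over the list alone. The lowest by moderated statistic, none past the threshold, were oppA (-2.60 ± 0.41), purA (-2.93 ± 0.52), purQ (-2.73 ± 0.51), purF (-2.34 ± 0.45) and purM (-2.45 ± 0.48). Pyrimidine genes had a median of -2.20 (4.65e-10, adjusted p = 0.582 with an estimated correlation), ribosomal protein genes -1.37 (1.56e-19, adjusted p = 0.689 with an estimated correlation) and motility genes -0.62 (5.32e-13, adjusted p = 0.0297 with an estimated correlation). In all, camera called 6 lists higher and 12 lower, and 0 and 1 with an estimated correlation. The lone array was assumed to vary like those of the other phases, and 30 genes passed without the 200 min array and 197 without the 240 min array.

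From 260 min to the stationary phase, general stress genes lay lower as a list. All 40 members lay below 0, with a list median of -1.09 relative to all genes (camera adjusted p = 4.33e-32, adjusted p = 0.774 with an estimated correlation). Examples were ytxG (-2.26 ± 0.64) and the DNA-protecting ferritin gene dps (-2.06 ± 0.60). Ribosomal protein genes lay on the other side, with 49 of 52 above 0 and a median of 0.58 (3.95e-11, adjusted p = 0.996 with an estimated correlation). All 10 pyrimidine genes lay above 0 (median 0.73, 0.00109, adjusted p = 0.996 with an estimated correlation), and heat shock genes had a median of -0.30 (0.00104, adjusted p = 0.774 with an estimated correlation).

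As single genes none passed (limma, Benjamini-Hochberg), and 52 had an unadjusted p under 0.05. By moderated statistic, again taken after the values were seen, yqaP (1.48 ± 0.43), yqgW (1.66 ± 0.52), sinR (1.19 ± 0.41), ypkP (1.25 ± 0.44) and dfrA (1.23 ± 0.46), which encodes dihydrofolate reductase, lay highest. The lowest were ykoK (-1.73 ± 0.37), ytxG, dps, yfkI (-1.51 ± 0.47) and yxiS (-1.31 ± 0.41). Camera called 4 lists higher and 5 lower, and none with an estimated correlation. Without the 200 min array 6 genes passed, and without the 240 min array 8.

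**Figure D3:**
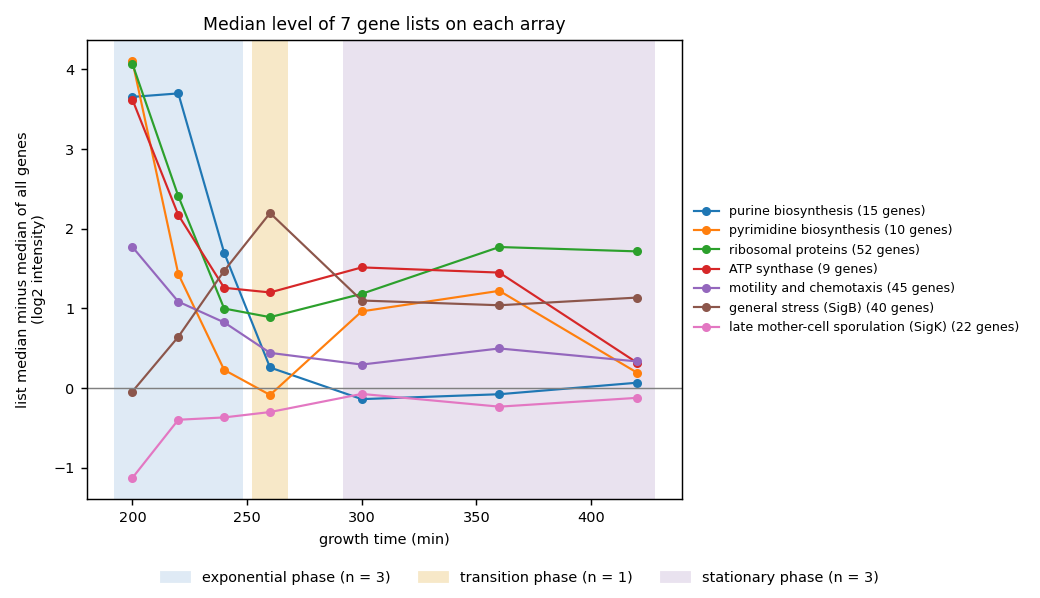
Median log2 intensity of the measured genes of 7 lists minus the median of all genes, against growth time in minutes, 1 point per array, with shading for the 3 phases. Pyrimidine, ribosomal protein and ATP synthase genes are highest at 200 min and purine genes at 220 min, and the general stress list is highest on the 260 min array.

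Within the exponential phase, the change per 20 min from 200 to 240 min was tested with a slope. The phase is that of the labels. Optical density rose from 0.55 to 1.05 and then to 1.36 in equal steps of time, so growth was not at a constant rate. The slopes therefore do not describe steady exponential growth. Ribosomal protein genes fell: 49 of 52 passed and 0 rose, or 50 adjusted over the list alone, with a median slope of -1.06 (camera adjusted p = 5.10e-59, adjusted p = 0.283 with an estimated correlation). The intensity of rplJ, which encodes ribosomal protein L10, went from 5470 at 200 min to 1911 and 368 (-1.92 ± 0.16 per 20 min over 3 arrays, SE from the shared trend). The SE of each slope in this fit comes from the spread shared by genes of similar level, not from the gene's own spread. That spread is departure from a straight line within a phase, with no replicate at any time. The p values of slopes therefore do not measure spread between replicate arrays. General stress genes rose: 35 of 40 passed and 0 fell, or 36 adjusted over the list alone (median slope 1.00, 3.65e-16, adjusted p = 0.283 with an estimated correlation). The largest rise of all was yheK (now nhaX), with 159, 680.2 and 2636 (1.96 ± 0.17).

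The next largest rises were yflT (1.90 ± 0.18), the general stress gene gspA (1.76 ± 0.16), yqgZ (1.75 ± 0.17) and ybyB (1.70 ± 0.19). The limma adjusted p of the 5 rises lay between 8.89e-28 and 3.27e-17 (Benjamini-Hochberg). After rplJ, the largest falls were rpsG (-1.91 ± 0.16), the lactate dehydrogenase gene lctE (now ldh, -1.90 ± 0.16), the dihydroorotase gene pyrC (-1.88 ± 0.18) and rplA (-1.86 ± 0.17). With rplJ, their limma adjusted p values lay between 1.06e-28 and 8.64e-22 (Benjamini-Hochberg). All 10 pyrimidine genes fell (median slope -1.40, camera adjusted p = 1.98e-24, adjusted p = 0.560 with an estimated correlation), as did all 9 ATP synthase genes (-0.78, 1.24e-08, adjusted p = 0.796 with an estimated correlation), and both counts were the same adjusted over the list alone. In the aminoacyl-tRNA synthetase list 16 of 21 fell (18 adjusted over the list alone, 1.44e-09, adjusted p = 0.595 with an estimated correlation), and 8 of 10 translation factor genes fell (8, 7.09e-09, adjusted p = 0.560 with an estimated correlation).

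Of 22 late SigK-dependent spore genes 20 rose and 1 fell (21 and 1 adjusted over the list alone, median slope 0.80, camera adjusted p = 0.00236, adjusted p = 0.796 with an estimated correlation), and of 51 CcpA-repressed sugar genes 41 rose and 1 fell (44 and 1, 0.000525, adjusted p = 0.796 with an estimated correlation). In the same test 294 of 606 intergenic probe sets rose and 14 fell, and the median slope of all genes was 0.35. Over all genes 1591 rose and 526 fell, of which 176 and 91 changed at least 2-fold per 20 min. Those counts depended on processing: with quantile normalization 339 rose and 407 fell, with equal array medians 649 and 1135, and without the 200 min array 15 and 79. With each array's intergenic median subtracted 0 rose and 1 fell, so that no ribosomal protein or general stress gene passed, at median slopes of -0.94 and 1.41. Without the 300, 360 or 420 min array 652, 648 or 631 rose, and the fit had 2 residual degrees of freedom with all genes taken to share the trend in spread. Under quantile normalization and equal medians 0 ribosomal protein genes rose (41 and 50 fell) and 0 general stress genes fell (33 and 20 rose). The mean log2 ratio of 3′ to 5′ signal, often read as a sign of RNA quality, also moved in step with the slopes. It was -0.650 at 200 min, -0.217 at 220 min and 0.0425 at 240 min. Single ratios differed: Lys read -0.818, 0.512 and 0.475 and Trpn 0.048, 0.043 and 0.648, while Dap, Phe and Thr rose at each step. These transcripts are named after B. subtilis genes, so their own transcription may also move the ratios, which was not tested.

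Within the stationary phase, the change per 60 min from 300 to 420 min was tested in the same way. The largest rise was that of yqeZ, which went from 1149 at 300 min to 2640.0 and 8537 (1.44 ± 0.17 per 60 min over 3 arrays, SE from the shared trend). Its neighbour yqfA (1.38 ± 0.16), yvlB (1.34 ± 0.16) and yknW (1.26 ± 0.16) came next. With yqeZ, they are genes of the cell envelope stress regulon of SigW. After them came yqgK of the pst operon (1.25 ± 0.17). The limma adjusted p values of these rises lay between 3.22e-14 and 3.71e-11 (Benjamini-Hochberg). The largest falls were yqgA (-1.36 ± 0.17), atpB (-1.16 ± 0.16), the chaperonin gene groES (-1.16 ± 0.20), the aspartate aminotransferase gene aspB (-1.08 ± 0.16) and the acyl carrier protein gene acpA (-1.08 ± 0.16), with limma adjusted p between 6.67e-13 and 5.28e-07 (Benjamini-Hochberg).

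Of 9 ATP synthase genes 8 fell and 0 rose, or 9 adjusted over the list alone (median slope -0.74, camera adjusted p = 2.21e-16, adjusted p = 0.998 with an estimated correlation). Of 10 pyrimidine genes 5 fell, also adjusted over the list alone (-0.44, 3.24e-08, adjusted p = 0.998 with an estimated correlation), and of 13 fatty acid synthesis genes 4 fell (5 adjusted over the list alone, 0.000439, adjusted p = 0.998 with an estimated correlation). Without the 420 min array the medians relative to all genes turned to 0.21 for pyrimidine and 0.019 for fatty acid synthesis genes, and neither list passed (camera adjusted p = 0.925 and 0.933). All 5 pst genes rose, the only members of the phosphate starvation list that passed (7.18e-06, adjusted p = 0.998 with an estimated correlation), also adjusted over the list alone. The list's median slope was -0.081, slightly above the median of all genes (-0.102), which is the direction of the test. In the secondary metabolite list 4 of 31 rose, also adjusted over the list alone (camera pointing up, 0.0233, adjusted p = 0.998 with an estimated correlation). Its median slope was -0.047, above the -0.102 of all genes. Without the 420 min array the list did not pass (camera adjusted p = 0.251). Of 52 ribosomal protein genes 1 rose and 3 fell, with a median slope of 0.32 (1.02e-09, adjusted p = 0.998 with an estimated correlation) and 15 rises and 3 falls adjusted over the list alone.

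Over all genes 126 rose and 109 fell within the stationary phase (limma, Benjamini-Hochberg), 19 and 6 of them by at least 2-fold per 60 min. Among single arrays left out, the calls changed most without the last: 15 rose and 0 fell without 420 min (aspB then turned to 0.057), while 52 and 108 did without 300 min and 192 and 125 without 360 min. The split was 61 and 93 with quantile normalization and 34 and 4 with equal array medians, and no gene passed with the intergenic median subtracted.

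Possible signs of RNA quality were compared between the phases through probe sets for the 3′ and 5′ parts of 5 transcripts on the array. The transcripts (Dap, Lys, Phe, Thr and Trpn) are named after B. subtilis genes, so the ratios may also follow their transcription. The mean log2 ratio of 3′ to 5′ signal was -0.275 ± 0.350 in exponential and -0.0331 ± 0.0535 in stationary phase (SD, n = 3 each, exact permutation test, two-sided p = 0.4). At 200 min it was -0.650, the lowest of the 7 arrays. With 3 arrays against 3 the smallest p the test allows is 0.1, which was reached by 2 of the 5 single ratios. After Benjamini-Hochberg adjustment over the 8 measures compared, the lowest value of the exact tests was 0.4.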

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

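All tests in this part were chosen after the results they measure had been seen, except the test of distance from the replication origin, which was set down before its values were computed and to which the comparison with the middle of the chromosome was added after.

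Signal appeared in probe sets that no comparison of genes uses: the intergenic median reached 280.0 on the 300 min array, where the Bio and Cre control probe sets had a median of 2.02, and was lowest on the 200 min array (84.1). A different scale factor for that array is argued against by the ratio of its 95th to its 25th percentile, which a factor cannot move: it was 25.3, against 4.89 to 8.68 on the other arrays. An offset of the deposited values shared by all probe sets is argued against by the control probe sets. Their median rose by at most 11.0 over the 200 min array while the intergenic median rose by 109.9 to 195.8. The values are MAS5 signals, so background brightness before that processing cannot be judged from them. A template that follows gene copy number, such as DNA in the samples, stays open as a candidate explanation: the gain from 200 min to the mean of 220 and 240 min was 1.38 times higher in intergenic probe sets nearest the replication origin than in those farthest from it, with the chromosome divided into 3 equal stretches (95% bootstrap interval 1.13 to 1.54), but the middle stretch gained 160.9 against 136.0 near the origin, and the level at 200 min already differed by 2.42 times. Transcription of intergenic stretches that differs with growth was not tested.

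The general stress list peaked on the single transition array. Its median relative to all genes was 1.47 at 240 min, 2.20 at 260 min and 1.10 at 300 min. The higher floor of dim probe sets after 200 min is argued against as the whole cause of the rise from 200 to 260 min by its size, 2.35 on the log2 scale. It lay at percentile 100 of 10000 random lists matched on the level at 200 min (their central 95% lay between 0.39 and 1.00). Random genes were drawn independently, while the list's estimated correlation was 0.82, so this band is too narrow. The test does not cover the step from 240 to 260 min or the fall to 300 min. The change of growth phase stays open as an untested biological explanation, and an aberrant array at 260 min stays open as a technical one, since no other array of that time exists.

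The pst genes rose without the rest of the phosphate starvation list. The other 14 members had a median change of 0.095 (SD 0.14, highest 0.42), while the lowest pst change was 2.94. These 14 are the members that did not pass, so the values describe the pattern and are not a separate test of it. Some of them were dim, such as tuaH (203 at 300 min, where the intergenic median was 280.0), and others were brighter, such as phoR (744). The floor is argued against as the whole cause by the changes without the 200 min array: the lowest of the 5 was 2.23 and their median 2.72 (largest SE 0.44, largest limma Benjamini-Hochberg adjusted p = 0.000181), while the median of all genes was -0.062. Whether phosphate in the medium changed was not measured, and biological explanations were not tested.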

How the results depend on the processing

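The alternatives below were set before the data were examined, except for subtraction of the intergenic median, which was chosen after seeing them. Between stationary and exponential phase 25 genes rose and 55 fell. The counts were 16 higher with a pseudocount of 1, 9 higher with the filter, 107 and 120 with quantile normalization, 0 and 12 with equal medians, 0 and 12 without the trend, 659 and 545 with slopes within phases, 123 and 116 with a linear trend in time and 468 and 377 with one in optical density. Without 1 array they ranged from 0 to 215 higher and 11 to 301 lower. All 80 genes kept their direction in these omissions, and 11 passed in each. With the intergenic median subtracted 22 rose and 53 fell, and 30 of the 80 were among them. With slopes the median residual SD was 0.26, against 0.47 without them, and the causes of the other differences were not tested. Lists called (16) became 8 with the intergenic median subtracted and 1 with an estimated correlation, and ranged from 9 to 21 without 1 array. Between transition and exponential phase 0 genes became 3 with the intergenic median subtracted and 0 to 197 without 1 array, and 18 lists became 1 with an estimated correlation and 9 to 22 without 1 array. Between stationary and transition phase 0 genes became 2 and 0 to 8 in the same way, and 9 lists became 3 with equal medians, 0 with an estimated correlation and 6 to 10 without 1 array. Both comparisons gave no value without the transition array.

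Within the exponential phase 1591 rises became 339 with quantile normalization, 649 with equal medians, 0 with the intergenic median subtracted and 15 to 2004 without 1 array, and 526 falls became 1135 with equal medians, 1 with the subtraction and 79 to 563 without 1 array. The 19 lists became 0 with an estimated correlation, where camera had only 2 degrees of freedom, and 14 to 23 without 1 array. After subtraction the median ribosomal protein slope was -0.94 (median SE 0.23), against -1.06 (0.17), and the general stress slope 1.41 (0.20) against 1.00 (0.19). The prior degrees of freedom went from infinite to 0.958, so that genes no longer shared the spread of the trend. Within the stationary phase 126 rises became 61 with quantile normalization, 34 with equal medians, 75 without the trend, 0 with the subtraction and 15 to 192 without 1 array, and 109 falls became 4 with equal medians, 34 without the trend, 0 with the subtraction and 0 to 125 without 1 array. The 8 lists became 0 with an estimated correlation, again at 2 degrees of freedom, and 7 to 11 without 1 array.

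Medians relative to all genes turned in few lists. Between stationary and exponential phase, ribosomal proteins ranged from -1.52 to 0.24 without 1 array (0.24 without 200 min), and the general stress list from -0.26 to 0.37 (0.37 without 240 min, and 0.24 with optical density, both then past the camera threshold at the preset correlation). The phosphate starvation list, near 0, turned to 0.091 with the filter, 0.065, 0.013 and 0.061 without the 220, 240 and 360 min arrays (lowest -0.082), and 0.0044 and 0.063 with time and optical density. Within the stationary phase the turns all came without the 420 min array: pyrimidine genes to 0.21 (lowest -0.97), fatty acid synthesis to 0.019 (lowest -0.37), secondary metabolites to -0.043 (highest 0.13), phosphate starvation to -0.061 and the gene aspB to 0.057 (lowest -2.23). Beyond stationary against exponential phase only lists with values in the text were followed, a selection made after turns of others had been seen. Scaling moved the median of all genes from 0.17 to 0.0022 (quantile) or 0.022 (equal medians) between stationary and exponential phase, and from 0.35 to 0.041 or -0.093 within the exponential phase. No paired analysis was possible because each time point had 1 array and the labels pair no arrays.

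Among the 10 splits of the 6 exponential and stationary arrays into 3 and 3, 1 (the real one) gave 80 genes and the highest other gave 0. The splits are too few for a share under 0.05.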

Other observations

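The genes of this paragraph were chosen after their values were seen, while the tests of SigW and PurR genes below were written down before the genes they measure had been looked at, on lists made after the pattern was seen. Genes outside the lists also fell between exponential and stationary phase. The serine synthesis gene serA (-1.81 ± 0.33), the aromatic amino acid genes aroF (-1.49 ± 0.30), aroH (-1.40 ± 0.28) and aroA (-1.39 ± 0.31), the quinol oxidase gene qoxA (-1.64 ± 0.37) and the genes lytA (-1.96 ± 0.42) and lytB (-1.78 ± 0.31) of the autolysin operon fell, with limma adjusted p values of 0.0217, 0.0337, 0.0315, 0.0481, 0.0496, 0.0419 and 0.0198 (Benjamini-Hochberg). Among rises outside the lists were ymcA (1.58 ± 0.36), a gene needed for biofilm formation, its neighbour ymcB (1.60 ± 0.35), and spoIISA (1.41 ± 0.30), which encodes a toxin, with limma adjusted p of 0.0492, 0.0453 and 0.0374 (Benjamini-Hochberg). Without the 360 min array or without the 420 min array no rise passed, while the lowest changes without 1 array were 1.41 for ymcA, 1.45 for ymcB and 1.25 for spoIISA.

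The rise of yqeZ, yqfA, yvlB and yknW within the stationary phase led to the hypothesis that genes known to be transcribed with SigW, a sigma factor of cell envelope stress, rose more widely. Over 40 SigW genes other than 7 noticed before, the median slope was 0.37 per 60 min. It lay at percentile 100 of 10000 random lists matched on mean level (their central 95% lay between -0.15 and -0.03). In that set 12 genes rose and 0 fell, and 36 had a slope above 0. Among them sigW itself had a slope of 0.80 ± 0.16 and yuaG of 1.15 ± 0.22, with limma adjusted p = 5.21e-05 and 2.19e-05 (Benjamini-Hochberg). The yteI slope was -0.34 ± 0.16. Some of the 40 share an operon with the genes noticed before, such as yvlD and yknX, or with each other, and are not independent. Random genes were drawn independently, so the band of the random lists is too narrow. The median of the 40 stayed above that of all genes by 0.46 with quantile normalization (11 genes called). With the intergenic median subtracted it stayed above by 0.68 (0 called). Without the 420 min array the median slope was 0.049, above that of all genes by 0.23, and 0 genes were called. A SigW-dependent response late in stationary phase is consistent with these values, and may be looked for in cultures sampled after 360 min.

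The fall of the purine operon led to the hypothesis that other genes known to be repressed by PurR, the purine repressor, fell too. Beside the genes noticed before (yumD, yqhZ, glyA and purT, which all fell), 6 genes were tested: xpt, folD, pbuX, purR, yebB and ytiP. Their median change was -1.63, at percentile 0 of 10000 random lists matched on mean level (-0.49 to 0.41), and all 6 were below 0. The genes xpt and pbuX share an operon and folD lies beside yqhZ, so that the 6 are not independent of each other or of the genes noticed before. Random genes were drawn independently, so the band of the random lists is too narrow. None of the 6 passed over all genes, with limma adjusted p from 0.0504 for xpt to 0.308 for ytiP (Benjamini-Hochberg). A wider change of PurR-repressed genes may therefore accompany the fall of the operon, as a hypothesis from the same arrays, and whether PurR acted in these cells was not measured.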
